A study of Homo sapiens with 12 samples.

How the data were processed

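Bulk RNA was sequenced as read pairs from 12 samples of Caco-2 spheroids, 3 in each of 4 groups: control, methotrexate, lactoferrin and methotrexate with lactoferrin. Per the labels, the tools behind the processing were CASAVA, STAR and DESeq2 with the human build hg19, and the submitters called genes with DESeq2 at a change over 2-fold and an adjusted p under 0.01. The versions of these tools, their roles, the gene annotation and the counting program are not given in the sources used here. The deposited table holds integer counts for 48162 genes in 12 columns, 1 per sample, of which 15233 genes are 0 throughout, and its values were whole numbers as counts should be. Whether a count stands for a read or a read pair, and whether the libraries keep strand, is not given in the sources used here. Counts of antisense genes such as TRHDE-AS1 and TMPO-AS1, and of close paralogs such as the histone, metallothionein and AKR1C genes, may therefore include fragments of their neighbours. Gene identifiers, symbols and hg19 coordinates were taken from the table itself.

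Library totals ran from 18714054 to 60591667 counts, so that 3 counts correspond to 0.16 to 0.0495 CPM. Intervals and floors built from counts cover counting error only, since reads without molecular identifiers are not independent molecules.

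Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr on the 4 groups, which left 16733, and libraries were scaled with TMM, giving factors of 0.852 to 0.884 for the methotrexate libraries and 1.01 to 1.08 for the others. A negative binomial model with 1 mean per group was fitted to all 12 samples, with a biological coefficient of variation of 12.9%, 8 residual degrees of freedom and a median of 15.6 total degrees of freedom after moderation. The quasi-likelihood F test was applied to 6 contrasts: methotrexate against control, lactoferrin against control, both agents against control, both against methotrexate, both against lactoferrin, and the interaction. P-values were adjusted by Benjamini-Hochberg within each contrast and called under 0.05.

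The gene lists, the rule for named genes, the tests and most alternatives were set before the data were examined. The rule takes the 10 genes with the largest rise and the 10 with the largest fall among those called, with an average log2 CPM of at least 1 and no overlap between the libraries of the groups compared. For the interaction no rule on overlap applies. In addition, up to 4 members with the lowest p from each list and the genes always given (TYMS, TFRC, FTH1, LTF, CDKN1A, MKI67 and LGR5) are named. Names of uncharacterised clones were passed over. Single-gene results of some genes under this rule are not reported here, though these genes stay in the fits, the counts and the lists. Where a group had 0 counts for a gene, its fold is a lower bound against 3 counts over the whole group, and with 1 to 3 counts the ratio is given with its 95% counting interval. Fitted log2 values of such genes depend on the prior count.

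A set of 38 gene lists covered folate and nucleotide metabolism, cell cycle and stress responses, iron handling, signalling, enterocyte functions and markers of other cell types. The 34 with at least 5 tested members were tested with camera (limma 3.58.1, through edgeR) on normal scores of the counts under the negative binomial fit, at the preset correlation of 0.01 and again with a correlation estimated from the residuals, with Benjamini-Hochberg adjustment over lists. Members were counted as called over all genes and adjusted over the list alone.

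The pipeline was first tested on simulated data with 15094 genes. For methotrexate against control, it recovered 56.7% of changes of 1.5-fold, 91% of 2-fold and 100% of 4-fold, and for the interaction 27.6, 73.1 and 97%. Between 8 and 20 of the unchanged genes were called in contrasts with true changes and 0 of 15094 in the contrast without any. The changed genes, 66 or 67 per fold and agent, were drawn from genes above a minimum CPM in control and went up or down at random. No mass of extra transcripts was simulated, so these rates need not hold for comparisons with the methotrexate libraries.

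The alternatives included the submitters' threshold applied to the edgeR results, DESeq2 1.42.0 with its Wald test, relative log expression factors and limma-voom. The others were no filter, a term for the replicate number, a fit of the compared groups alone and leaving out each library in turn. Added after seeing the data were a fit without the methotrexate libraries, scaling on the median ratio of the brush border and tight junction genes, and thinning the methotrexate libraries to the mean depth of the other 9. Other splits of the samples into groups of the same sizes were also tested, up to 100 per result. No sample was left out of the main comparisons, and no sequence reads were available.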

Results

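RNA was sequenced from spheroids of Caco-2, an established human colorectal adenocarcinoma line that takes on features of absorptive enterocytes in culture. The cells, at passage 26, grew in Matrigel for 5 days in medium with 20% fetal bovine serum. They were then exposed for 4 h to carrier fluid (control), to methotrexate, to lactoferrin or to both agents, with 3 libraries in each of the 4 groups. Methotrexate is an antifolate drug, and lactoferrin is an iron-binding protein of milk and mucosal secretions. The 6 comparisons ask what each agent alone, the pair and the addition of one agent to the other do to transcript levels.

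The control libraries held 19892094, 23859094 and 23338317 counts and the lactoferrin libraries 19994882, 18842041 and 18714054. Those with both agents held 22710347, 19644459 and 20286550. The methotrexate libraries were deeper, at 47459811, 60591667 and 57029030 counts. They held counts for 26285 to 27433 genes, against 21385 to 22520 in control. Mitochondrially encoded genes took 6.67, 7.54 and 7.54% of their counts, against 2, 2.5 and 3.34% in control, 2.43 to 2.98% with lactoferrin and 2.56 to 2.73% with both agents. The 10 most abundant genes took 9.52 to 10.2% of the counts with methotrexate and 5.2 to 6.07% in the other 9 libraries. A gene with no count in a library may be present there at up to 0.0495 CPM in the deepest library and 0.16 CPM in the shallowest (3 counts of the total, counting error only). Nothing in the sources used here states that the 3 libraries of a group came from separate cultures, so the p-values measure spread between these samples, which may be technical in part. Levels below are CPM after TMM scaling, as mean ± SD with n = 3, and changes are log2 fold changes ± SE.

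Methotrexate libraries carried abundant transcripts that control spheroids hardly held. COL15A1 (ENSG00000204291, chromosome 9, 101705461 to 101833069 on hg19), a basement membrane collagen, had 0 counts in the 3 control libraries and 137 ± 10.8 CPM with methotrexate, at least 3150-fold higher. ADIPOQ (ENSG00000181092, chromosome 3, 186560463 to 186576252), which encodes the hormone adiponectin, had 5 counts in all of control and 1560 ± 53.4 CPM with methotrexate, a change of 14.31 ± 0.32. CDKN1A (ENSG00000124762, chromosome 6, 36644305 to 36655116), an inhibitor of cyclin-dependent kinases and a p53 target, rose from 17.6 ± 2.12 to 1030 ± 45.5 CPM, by 5.88 ± 0.12. The falls were far smaller, and the lowest log2 fold change among the genes named by rule was -1.59 ± 0.32, for the zinc transporter SLC30A2 (3.83 ± 0.676 to 1.28 ± 0.595 CPM). TYMS (ENSG00000176890, chromosome 18, 657604 to 673578), the thymidylate synthase of DNA synthesis and itself a target of antifolates, fell by 1.06 on the log2 scale, from 46 ± 2.78 to 22 ± 0.987 CPM, and is no longer called under the epithelial scaling described next (-0.19, adjusted p = 0.12).

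Of 16733 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 10791, with 5922 higher and 4869 lower (54.9% higher). The cut-offs of the study's own rule, a change over 2-fold at an adjusted p under 0.01, were applied to these edgeR results and not to DESeq2. They held 4525 genes, with 3607 higher and 918 lower. The direction of much of this set depends on how the libraries are scaled. With TMM the median log2 fold change of all tested genes was 0.03. When libraries were instead scaled on 42 genes of the brush border and tight junction lists, an alternative chosen after seeing the data and called epithelial scaling here, that median shifted to 0.91. No list test was run with it, so the adjusted p of a list never refers to its median under this scaling. The gene test with it called 12432 genes, of which 98.9% were higher and 140 lower, and 7791 of them were also called with TMM, in either direction. No overlap between the 3 libraries of either group was seen for 7848 genes that also passed the test, the abundance limit and the rule on gene names. Chance separates 3 from 3 in 10% of all genes, a rate that does not apply to genes already called.

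Among the 10 named genes with the largest rises, 9 had no count in control. PCDH18, a protocadherin (ENSG00000189184, chromosome 4, 138440072 to 138453648), was at least 4200-fold higher, ADAMTS2, a procollagen peptidase, at least 3420-fold and the lectin gene FCN1 at least 2220-fold. C14orf180 was at least 2090-fold higher, the microfibril gene MFAP5 at least 1800-fold, the collagen gene COL8A1 at least 1670-fold, the matrix gene DPT at least 1390-fold and TRHDE-AS1 at least 1360-fold. Of the 20 genes with the largest rises and falls, 17 were still called under epithelial scaling. That scaling raises all genes by less than any of these falls, so the directions were fixed and only the calls of the falls were put to a test. The 10 largest falls lay between -1.59 and -1.50. They included ASAH2 (ENSG00000188611), the neutral ceramidase of the gut, at -1.57 ± 0.18 (-0.70 under epithelial scaling), the kinase SYK at -1.56 ± 0.23 (-0.68) and the intestinal homeobox factor ISX at -1.56 ± 0.39 (-0.69, adjusted p = 0.0931). EDN3 (-1.55), IGSF23 (-1.53), HTR1D (-1.53), DMRTA2 (-1.53), P2RY6 (-1.51) and the long noncoding RNA UCA1 (-1.50 ± 0.22) completed them.

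**Figure D1:**
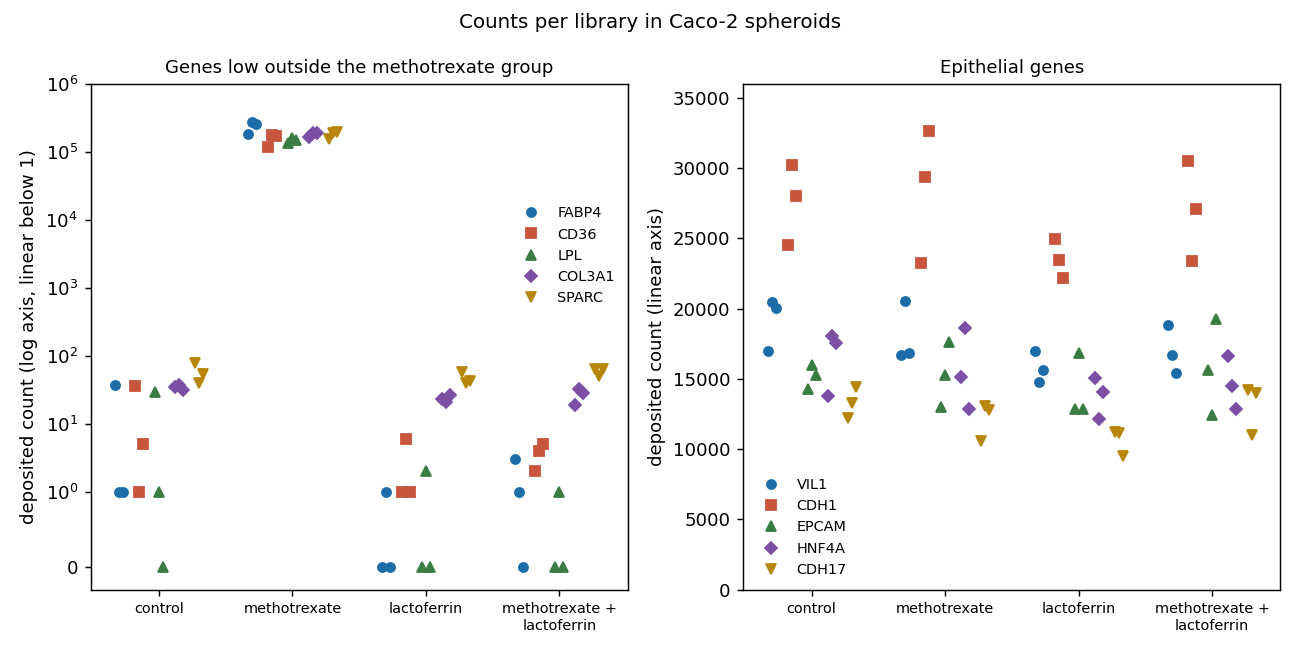
Deposited counts per library in the 4 groups, 1 point per library; the left panel has a log axis that is linear below 1 and the right panel a linear axis from 0. FABP4, CD36, LPL, COL3A1 and SPARC had 118089 to 273766 counts in methotrexate libraries and 0 to 77 in the other 9, while VIL1, CDH1, EPCAM, HNF4A and CDH17 had 10591 to 32632 counts with methotrexate and 9535 to 30507 elsewhere.

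Genes of folate and nucleotide metabolism went both ways with TMM scaling, in methotrexate libraries that also carried fibroblast markers. Of 20 folate cycle genes, 7 rose, 4 fell and 9 were not called, with the same 7 and 4 adjusted over the list alone and a median of 0.03 (adjusted p = 0.63), or 0.91 with 17 up and 0 down under epithelial scaling. ALDH1L1, a 10-formyltetrahydrofolate dehydrogenase, rose by 9.19 ± 0.21, from 0.955 to 566 CPM, and the serine hydroxymethyltransferase SHMT1 by 1.43 ± 0.09. Of 15 genes of methotrexate transport and polyglutamation, 2 rose and 10 fell, also adjusted over the list alone, with a median of -0.89 (adjusted p = 0.0372, and adjusted p = 0.324 with an estimated correlation) that came to -0.01 under epithelial scaling. The efflux pumps ABCC2 (-1.23 ± 0.10, 184 to 78.8 CPM) and ABCG2 (-1.17 ± 0.11) fell, or were at -0.35 and -0.29 under epithelial scaling, and the oxidase AOX1 rose by 5.75 ± 0.18. Purine synthesis had 3 up and 8 down of 15, also adjusted over the list alone, and a median of -0.30 (adjusted p = 0.103), or 0.58 under epithelial scaling. Pyrimidine and deoxynucleotide synthesis had 3 up and 10 down of 18, also adjusted over the list alone, and a median of -0.50 (adjusted p = 0.0552), or 0.38 under epithelial scaling. Adenosine handling had 6 up and 3 down of 14, or 7 up adjusted over the list alone, and its median (0.25) and mean (0.22) were above 0 while the list test pointed down (adjusted p = 0.816). Epithelial scaling gave 9 up, 0 down and a median of 1.13 for it, with 6 up and 2 down for transport, 11 up and 0 down for purine and 11 up and 1 down for pyrimidine synthesis. The transport list lost its call without methotrexate library 2 (adjusted p = 0.0567, and 0.000298 to 0.324 over all alternatives). The pyrimidine list gained one without control 2 (0.0382) or methotrexate 1 (0.0376), within 0.00134 to 0.248.

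Genes of the cell cycle were lower and p53 targets higher in the methotrexate libraries, in which the median of the fibroblast markers was also higher by 9.91. Of 26 p53 target genes, 21 rose and 0 fell (21 and 1 adjusted over the list alone), with a median of 0.90 and an adjusted p = 3.12e-06, or adjusted p = 0.0572 with an estimated correlation. PHLDA3, an AKT inhibitor, rose by 8.40 ± 0.23 (0.964 to 327 CPM), the RNA-binding factor ZMAT3 by 2.54 ± 0.12 and the death receptor FAS by 8.06 ± 0.43. All 27 G2/M genes fell, also adjusted over the list alone, with a median of -1.13 (adjusted p = 2.36e-09, and adjusted p = 0.126 with an estimated correlation). That median came to -0.25 with 10 down and 0 up under epithelial scaling. The spindle factor TPX2 went from 388 ± 18.8 to 175 ± 7.68 CPM (-1.15 ± 0.08, -0.27 under epithelial scaling). MKI67, a proliferation marker, was at -1.13 ± 0.19, or -0.25 with adjusted p = 0.221 under epithelial scaling. Of 29 G1/S and replication genes 27 fell, also adjusted over the list alone, with a median of -0.95 (adjusted p = 1.78e-06, and adjusted p = 0.0572 with an estimated correlation), or -0.07 with 4 up and 2 down under epithelial scaling. GINS2 (-1.12 ± 0.09) and PCNA (-0.96 ± 0.09), both of the replication fork, were among them, at -0.24 and -0.08 (adjusted p = 0.0406 and 0.488) under epithelial scaling. DNA repair had 2 up and 21 down of 28, also adjusted over the list alone, with a median of -0.75 (adjusted p = 0.000264, and adjusted p = 0.126 with an estimated correlation) that turned to 0.13 under epithelial scaling. Histone genes had 9 up and 3 down of 15, also adjusted over the list alone, and a median of 1.17 (adjusted p = 0.0372, and adjusted p = 0.126 with an estimated correlation), led by HIST2H2BE at 5.01 ± 0.14. Apoptosis genes had 12 up and 7 down of 27, also adjusted over the list alone, with a median of 0.10 (adjusted p = 0.539), or 0.98 with 22 up and 0 down under epithelial scaling. That scaling gave p53 targets 26 up, 0 down and a median of 1.79, histone genes 12 up, 1 down and 2.05, and DNA repair 11 up and 0 down.

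Several stress and survival lists were higher with methotrexate, beside fibroblast markers and mitochondrial shares of 6.67 to 7.54%. Of 18 NRF2 targets, 13 rose and 2 fell, also adjusted over the list alone, with a median of 0.92 (adjusted p = 0.000316, and adjusted p = 0.0572 with an estimated correlation), among them malic enzyme ME1 (4.85 ± 0.14, 60.6 to 1750 CPM) and heme oxygenase HMOX1 (4.28 ± 0.14). The integrated stress response had 19 up and 7 down of 30 (20 and 7 adjusted over the list alone), a median of 0.67 and an adjusted p = 0.0349, or adjusted p = 0.324 with an estimated correlation. Its regulator NUPR1 rose by 8.36 ± 0.20 (1.41 to 462 CPM) and ATF3 by 4.36 ± 0.22. Autophagy and lysosome genes had 13 up and 2 down of 19 (14 and 2 adjusted over the list alone) with a median of 0.86 (adjusted p = 0.00433, and adjusted p = 0.126 with an estimated correlation). Hypoxia and glycolysis genes had 15 up and 3 down of 23 (15 and 4 adjusted over the list alone) with a median of 0.55 (adjusted p = 0.0117, and adjusted p = 0.324 with an estimated correlation). The unfolded protein response had 3 up and 12 down of 19, also adjusted over the list alone, with a median of -0.35 (adjusted p = 0.0349, and adjusted p = 0.152 with an estimated correlation) that turned to 0.53 under epithelial scaling. Heat shock genes had 3 up and 8 down of 17, also adjusted over the list alone, with a median of -0.24 (adjusted p = 0.103), or 0.64 under epithelial scaling. Metallothionein and zinc genes had 3 up and 1 down of 7, also adjusted over the list alone (median 0.30, adjusted p = 0.77), with MT2A at 4.19 ± 0.21. Iron handling had 10 up and 8 down of 19, also adjusted over the list alone (median 0.28, adjusted p = 0.0612). Under epithelial scaling it had 13 up, 0 down and a median of 1.16. The integrated stress response then had 25 up, 0 down and a median of 1.55, NRF2 targets 17 up, 1 down and 1.80, autophagy 19 up, 0 down and 1.74, and hypoxia genes 21 up, 0 down and 1.42. Metallothionein genes had 5 up, 1 down and 1.18, the unfolded protein response 15 up and 0 down, and heat shock genes 12 up and 0 down. The serum iron carrier TF rose by 8.40 ± 0.21 (6.93 to 2340 CPM), the ferritin heavy chain FTH1 by 2.06 ± 0.26 and LTF, the lactoferrin gene itself, by 3.73 ± 0.42 (0.399 to 5.56 CPM), whereas the transferrin receptor TFRC was at -0.85 ± 0.11, or 0.03 (adjusted p = 0.819) under epithelial scaling. The stress response list lost its call without methotrexate 1 (adjusted p = 0.066, and 7.62e-06 to 0.324 over all alternatives). The iron list gained one without lactoferrin 1 (0.0384) or methotrexate 2 (0.046), within 2.61e-05 to 0.35.

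Signalling lists moved with methotrexate as well, again in libraries with fibroblast and endothelial markers. Of 32 immediate early and MAPK feedback genes, 26 rose and 4 fell (27 and 4 adjusted over the list alone), with a median of 2.07 (adjusted p = 2.95e-05, and adjusted p = 0.126 with an estimated correlation), among them the AP-1 subunit JUN (4.09 ± 0.14, 13.3 to 227 CPM). Of 18 TGF-beta, BMP and YAP targets, 13 rose and 1 fell, also adjusted over the list alone, with a median of 1.35 (adjusted p = 0.000336, and adjusted p = 0.248 with an estimated correlation). NF-kB and inflammatory genes had 15 up and 4 down of 26, also adjusted over the list alone (median 0.52, adjusted p = 0.103), and interferon-stimulated genes 13 up and 2 down of 21, also adjusted over the list alone (median 0.55, adjusted p = 0.0984). SOD2 (2.53 ± 0.10) and IFI6 (4.04 ± 0.19) were examples. Of 19 Wnt targets and intestinal stem cell genes, 3 rose and 15 fell, also adjusted over the list alone, with a median of -0.93 (adjusted p = 0.037, and adjusted p = 0.283 with an estimated correlation), or -0.05 with 5 up and 3 down under epithelial scaling. Epithelial scaling brought the MAPK list to 28 up, 0 down and a median of 2.95, TGF-beta, BMP and YAP targets to 17 up, 0 down and 2.22, NF-kB genes to 23 up, 0 down and 1.40, and interferon genes to 18 up, 0 down and 1.43. The stem cell receptor LGR5 was at -1.32 ± 0.12 (22.8 to 9.13 CPM), and at -0.44 with adjusted p = 0.00573 under epithelial scaling, while the adhesion receptor CD44 rose by 4.64 ± 0.13.

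Epithelial lists were lower and lipid lists higher in the methotrexate libraries, where ADIPOQ (14.31) and the fibroblast markers (median 9.91) were higher as well. Of 23 brush border genes, 4 rose and 18 fell, also adjusted over the list alone, with a median of -1.05 (adjusted p = 0.00732, and adjusted p = 0.248 with an estimated correlation). The microvillus protein VIL1 went from 828 ± 17.2 to 381 ± 41.2 CPM (-1.12 ± 0.10, -0.24 under epithelial scaling). Of 19 tight junction and adhesion genes, 2 rose and 15 fell, also adjusted over the list alone, with a median of -0.99 (adjusted p = 0.000207, and adjusted p = 0.0572 with an estimated correlation), and E-cadherin CDH1 went from 1190 ± 20.5 to 597 ± 44 CPM. Epithelial scaling is built on both lists and leaves their medians at -0.16 (5 up, 1 down) and -0.11 (6 up, 3 down), with CDH1 at -0.11 (adjusted p = 0.254). Intestinal lipid handling had 11 up and 6 down of 19, also adjusted over the list alone, and a median of 0.87 (adjusted p = 0.000159, and adjusted p = 0.0572 with an estimated correlation). The desaturase SCD rose by 4.11 ± 0.09, from 1520 ± 20.1 to 26200 ± 822 CPM, and the lipid droplet protein PLIN2 by 4.60 ± 0.12. Cholesterol synthesis had 16 up and 4 down of 23, also adjusted over the list alone, and a median of 0.66 (adjusted p = 0.046, and adjusted p = 0.217 with an estimated correlation). Its call ended without control 1, control 2 or library 1 with both agents (adjusted p = 0.0502, 0.0622 and 0.054, within 1.18e-05 to 0.217 over all alternatives). Ribosome biogenesis had 22 down of 27 and ribosomal proteins 19 down of 26, also adjusted over the list alone, with 0 up in each. Their medians of -0.58 and -0.38 (adjusted p = 0.000282 and 0.00285, and adjusted p = 0.2 and 0.324 with an estimated correlation) turned to 0.30 and 0.50 under epithelial scaling. Of 13 mitochondrially encoded genes 12 rose, also adjusted over the list alone, with a median of 1.67 (adjusted p = 0.000264, and adjusted p = 0.248 with an estimated correlation). The 26 nuclear-encoded oxidative phosphorylation genes had 11 up and 2 down (10 and 2 adjusted over the list alone), and a median (0.18) and mean (0.14) above 0 where the list test pointed down (adjusted p = 0.817). Under epithelial scaling they had 25 up, 0 down and a median of 1.06, lipid handling 12 up, 1 down and 1.76, cholesterol synthesis 21 up, 0 down and 1.54, and mitochondrially encoded genes 13 up, 0 down and 2.55. Ribosome biogenesis and ribosomal proteins then had 16 and 23 up, with 0 down.

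Markers of other cell types were measured beside these groups. All 11 fibroblast markers rose with methotrexate, also adjusted over the list alone, with a median of 9.91 (9.55 with sparse genes at their bound), an adjusted p = 6.83e-37 and an adjusted p = 6.69e-05 with an estimated correlation. COL3A1 (ENSG00000168542), a fibrillar collagen, went from 1.48 ± 0.16 to 3780 ± 181 CPM, by 11.32 ± 0.17. All 4 endothelial markers rose, with a median of 5.04 (3.41 at the bound), and the angiopoietin receptor TEK was at least 63.8-fold higher. Of 4 immune markers 2 rose and 2 fell (median 0.18), with CD14 at 1.12 ± 0.13 and CD74 at -1.10 ± 0.15. The rise of PTPRC lost its call without control 2, control 3 or methotrexate 3 (adjusted p = 0.0888, 0.0837 and 0.103). Epithelial scaling gave 2 up, 0 down and a median of 1.06 for the immune markers, with CD74 at -0.22 (adjusted p = 0.197). Goblet cell markers had 0 up and 5 down of 8, also adjusted over the list alone, with a median of -0.94 (adjusted p = 0.031, and adjusted p = 0.126 with an estimated correlation), or -0.06 with none called under epithelial scaling. The enteroendocrine markers had 1 up and 1 down of 4 (median -0.56, or 0.32 under epithelial scaling, and mean 0.47) and the Paneth cell markers 1 up and 2 down of 4 (median -1.03, or -0.15). ITLN2 lost its call without control 1 or 2 (adjusted p = 0.0988 and 0.0892) or methotrexate 1 or 2 (0.0661 and 0.106). REG3A gained one without methotrexate 3 (0.0304), and INSM1 without control 1 (0.0193) or methotrexate 1 (0.0299). Of the 34 lists with at least 5 tested members, camera called 12 up and 11 down, and with an estimated correlation it called only the fibroblast markers. Epithelial scaling raises the genes of the methotrexate libraries alike, so a median above 0 stays above 0 by construction.

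**Figure D2:**
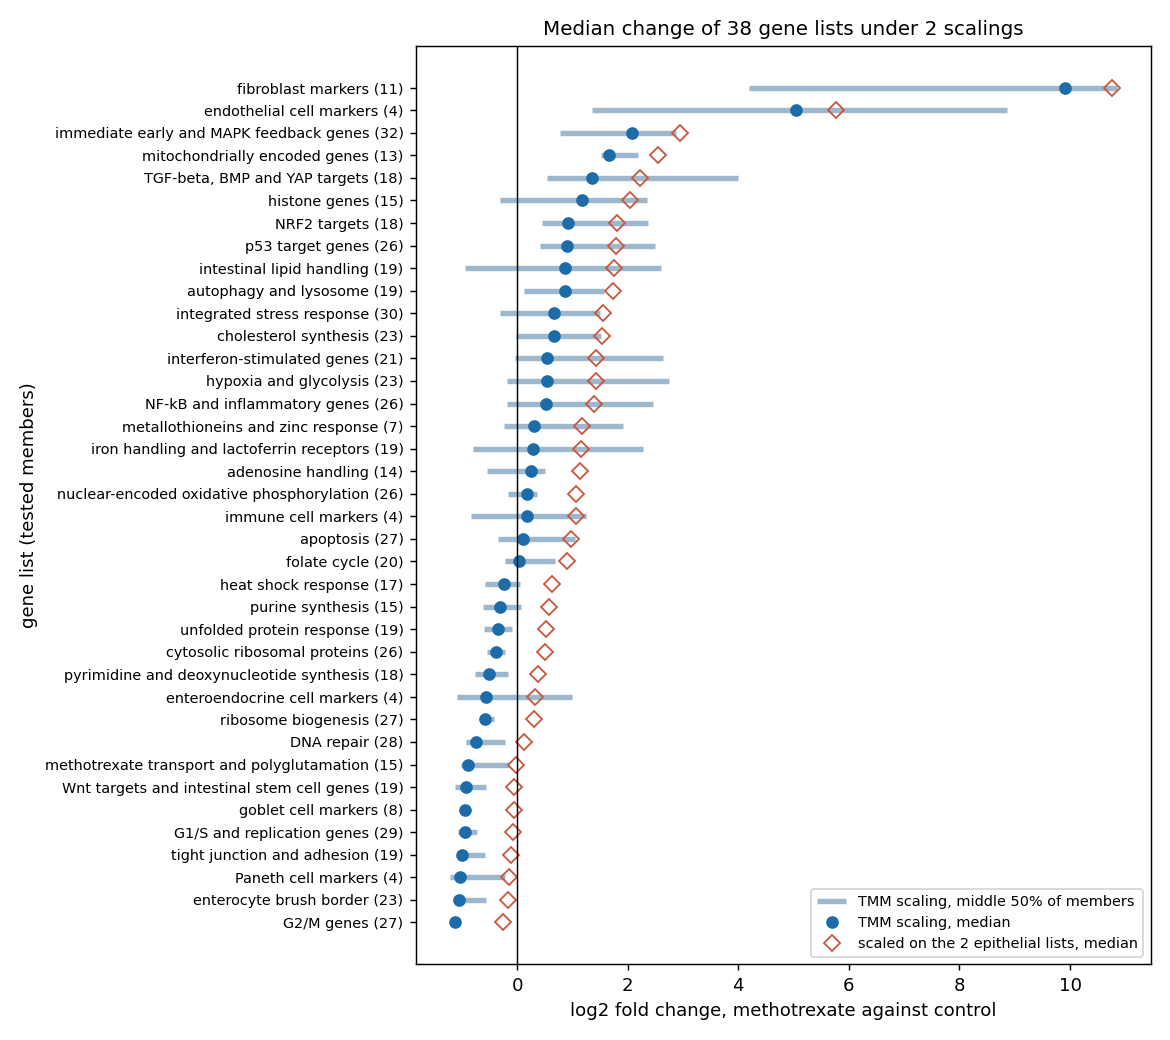
Median log2 fold change, methotrexate against control, of 38 gene lists with the number of tested members in parentheses; filled points are TMM medians with bars over the interquartile range of members, and open diamonds are medians under epithelial scaling. Fibroblast markers lie at 9.91, and the scaling moves ribosome biogenesis from -0.58 to 0.30 and G2/M genes from -1.13 to -0.25.

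Lactoferrin alone was compared with control to ask what the protein does without the drug. No gene passed the edgeR test. SPRY4 (ENSG00000187678), which restrains receptor tyrosine kinase signalling, was at 21.8 ± 0.95 CPM with lactoferrin and 34.8 ± 3.44 in control (-0.67 ± 0.14, adjusted p = 1). Over all alternatives the adjusted p of SPRY4 ran from 0.00511 to 1, and it was called only without a filter on low counts. The ERK phosphatase DUSP6 was at 16.2 ± 2.23 against 24.6 ± 1.99 CPM (-0.60 ± 0.16, adjusted p = 0.0117 without a filter and within 0.0117 to 1), SPRY2 at 22.3 ± 1.23 against 28.1 ± 1.33 and the early growth response gene EGR1 at -0.46 ± 0.16. Of 32 immediate early and MAPK feedback genes 0 were called over all genes and 3 were down adjusted over the list alone, and the list's median was -0.16 (adjusted p = 0.000464, and adjusted p = 0.409 with an estimated correlation). That list lost its call without lactoferrin 1 (adjusted p = 0.0624, and 9.3e-06 to 0.409 over all alternatives).

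Camera called 6 further lists lower with lactoferrin, none with an estimated correlation and none with a member called over all genes. Oxidative phosphorylation had a median of -0.11 (adjusted p = 2.57e-06) and ribosomal proteins -0.14 (1.27e-05), both with adjusted p = 0.409 with an estimated correlation. NRF2 targets were at -0.08 (adjusted p = 0.00754), ribosome biogenesis at -0.06 (0.0103), purine synthesis at -0.07 (0.0282) and heat shock genes at -0.09 (0.0282), with adjusted p = 0.409, 0.573, 0.409 and 0.573 with an estimated correlation. Adjusted over the list alone, none of these 6 lists had a called member, whereas TGF-beta, BMP and YAP targets had 3 up, histone genes 1 up and p53 targets 1 down. NRF2 targets lost their call without control 3 (adjusted p = 0.143) or lactoferrin 1 (0.0557), and ribosome biogenesis without control 1 (0.0987), control 3 (0.0671) or lactoferrin 1 (0.0723). Purine synthesis lost it without control 1 (0.0671), control 3 (0.193), lactoferrin 1 (0.0961) or lactoferrin 3 (0.0622), and heat shock genes without control 1 (0.0987), control 3 (0.347) or any of the lactoferrin libraries (0.0961, 0.0512 and 0.0588). Without control 3, which had the highest mitochondrial share of its group (3.34%), the mitochondrially encoded (2.81e-09), fibroblast (0.0381), p53 (0.0127), integrated stress response (0.0127) and metallothionein (0.0234) lists gained a call, as did autophagy without control 2 (0.0261) and methotrexate transport without control 1 (0.0193). The adjusted p of these lists ran from 5.21e-12 to 0.969 over all alternatives.

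The test called 0 of 16733 genes for lactoferrin, and so did DESeq2 and limma-voom. An unadjusted p under 0.05 was found for 628 genes with edgeR and 553 with voom, where 837 would be expected by chance. DESeq2 gave 821, but it was run on all genes with a count, more than that expectation refers to. TYMS was at -0.10 ± 0.09, TFRC at -0.04 ± 0.11, FTH1 at 0.50 ± 0.25, LTF at 0.11 ± 0.57, CDKN1A at -0.03 ± 0.11, MKI67 at 0.32 ± 0.18 and LGR5 at -0.09 ± 0.12, each with adjusted p = 1. FTH1 was called only without a filter on low counts (adjusted p = 0.00732, within 0.00732 to 1 over all alternatives). The fibroblast median was -0.11, the endothelial median 0.08 and the immune median -0.03. At this depth, 2-fold changes set into simulated counts of genes above a minimum CPM in control were called in 88.1% of genes and 1.5-fold changes in 43.3%.

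**Figure D3:**
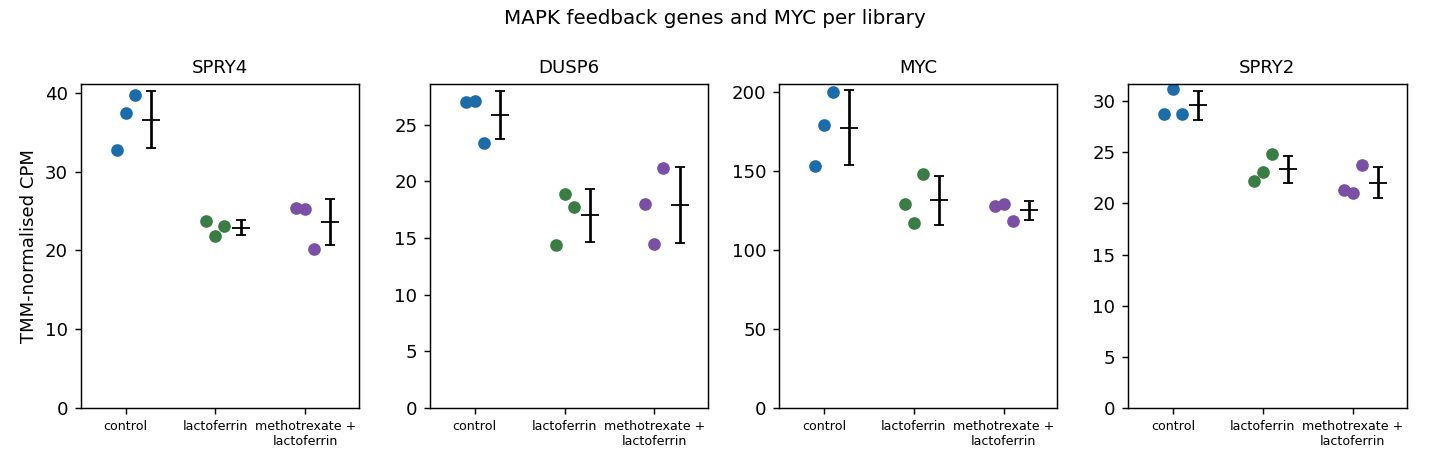
TMM-scaled CPM of SPRY4, DUSP6, MYC and SPRY2 in the 9 libraries outside the methotrexate group, scaled without that group; points are libraries, bars the mean ± SD with n = 3, and each axis starts at 0. SPRY4 lies between 32.7 and 39.7 CPM in control and between 20.2 and 25.4 in the 6 libraries with lactoferrin, a difference that the test over all genes did not call.

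Methotrexate with lactoferrin was compared with control, the setting in which the drug acts in the presence of the protein. VIM (ENSG00000026025, chromosome 10, 17270258 to 17279592), the intermediate filament protein vimentin, rose by 1.69 ± 0.20, from 0.637 to 2.06 CPM (adjusted p = 0.00339). MSN (ENSG00000147065, chromosome X, 64887537 to 64961791), which links actin to the membrane, rose by 2.14 ± 0.26, from 0.608 to 2.63 CPM (adjusted p = 0.00339). LGALS1 (ENSG00000100097, chromosome 22, 38071615 to 38075813), a galectin, rose by 1.53 ± 0.21 (adjusted p = 0.0133). AKAP12 (ENSG00000131016, chromosome 6, 151561134 to 151679692), a scaffold for protein kinase A, rose by 2.45 ± 0.36 (adjusted p = 0.0197). FBN2 (ENSG00000138829, chromosome 5, 127593601 to 127994878), a fibrillin, had 2 counts in control and 31 with both agents, a ratio of 16.3 with a counting interval of 4.14 to 140 (adjusted p = 0.0281). All 5 were scarce in both groups, with 7 to 21 counts per control library for MSN, and in the methotrexate libraries they stood at 689 (VIM), 216 (MSN), 945 (LGALS1), 68.6 (AKAP12) and 62.6 CPM (FBN2).

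These 5 were the only genes edgeR called, and each was also called higher with methotrexate alone, a comparison that shares the same 3 controls. DESeq2 called 15 genes and voom 0, and an unadjusted p under 0.05 was found for 591 genes with edgeR and 475 with voom, against 837 expected by chance. DESeq2 gave 753, on a larger set of genes to which that expectation does not apply. No gene was called when control 2 was left out, 3 were called without control 1 or without library 1 with both agents, and 8 without library 3 with both agents. VIM and MSN lost their call only without control 2 among the left-out libraries (adjusted p = 0.0512 for each), LGALS1 without control 2 (0.163) or control 3 (0.0872), and AKAP12 without control 1 (0.125), control 2 (0.2) or library 1 with both agents (0.0795). FBN2 lost it without any control (0.125, 0.212 and 0.122), lactoferrin 1 (0.0501), methotrexate 1 (0.0537) or 2 (0.0517), or library 1 (0.0904) or 2 (0.141) with both agents. Over all alternatives the adjusted p ran from 1.08e-09 to 0.681 for VIM, 3.19e-15 to 0.681 for MSN, 1.51e-11 to 0.743 for LGALS1, 5.17e-12 to 0.743 for AKAP12 and 4.75e-05 to 0.344 for FBN2. A fit without the 3 methotrexate libraries, added after seeing the data, called 0 genes, with 382 at an unadjusted p under 0.05, and so did a fit of the 2 compared groups alone, with 332.

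With both agents, none of the genes always given was called. TYMS was at 0.09, TFRC at 0.01, FTH1 at 0.32, LTF at 0.39, MKI67 at 0.23, LGR5 at 0.02 and CDKN1A at -0.27 ± 0.11. SPRY4 was at 22.5 ± 2.69 CPM (-0.63 ± 0.13, adjusted p = 0.309, within 0.00564 to 1 over all alternatives, and called by DESeq2 and without a filter), SPRY2 at -0.42 ± 0.10 (adjusted p = 0.605) and DUSP6 at -0.53 ± 0.16. SPRY2 was called by DESeq2 (adjusted p = 0.0361, within 0.0361 to 1 over all alternatives) and DUSP6 without a filter (adjusted p = 0.042, within 0.042 to 1). The immediate early and MAPK feedback list had 0 members called over all genes and 2 down adjusted over the list alone, with a median of -0.12 (adjusted p = 0.00146). Oxidative phosphorylation (-0.11), ribosomal proteins (-0.11), each with adjusted p = 0.000146, and ribosome biogenesis (-0.07, adjusted p = 0.0214) were also called lower, and all 4 lists had an adjusted p = 0.595 with an estimated correlation. Metallothionein genes had 2 up adjusted over the list alone, among them MT1G at 2.34 ± 0.58 (0.143 to 0.747 CPM, adjusted p = 0.671), and TGF-beta, BMP and YAP targets had 2 up. The fibroblast median was -0.07. The endothelial median of 1.56 is a fitted value that depends on the prior count, since 2 of its 4 members had no count in control, and none of the 4 was called.

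Of the list calls with both agents, that of the MAPK feedback genes was lost without library 2 with both agents (adjusted p = 0.0736), those of oxidative phosphorylation and ribosomal proteins without control 1 (0.236 each) or library 3 with both agents (0.23 and 0.112), and that of ribosome biogenesis without control 1 (0.274), control 3 (0.105) or library 1 with both agents (0.296). Calls were gained by NRF2 targets, purine synthesis, pyrimidine synthesis and the unfolded protein response without control 2 (0.0449, 0.0449, 0.0386 and 0.0386), and by metallothionein, p53 and mitochondrially encoded genes without control 3 (0.00177, 0.0174 and 1.56e-07). Hypoxia genes gained one without library 2 with both agents (0.0148) and purine synthesis without library 3 (0.0348). The adjusted p of these lists ran from 1.56e-07 to 0.998 over all alternatives.

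The changes of the groups with lactoferrin and with both agents share the same 3 controls. Across 13000 genes, which are not independent replicates, their log2 fold changes correlated at 0.532, against 0.492 (0.479 to 0.51) in 20 simulations where only the controls were shared. The covariance was 0.0208 against 0.0174, a difference of 0.00338. With 3 controls the shared part cannot be split off, so part of that excess may itself come from them.

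Adding lactoferrin to methotrexate asked whether the protein alters cells that also receive the drug. Both groups compared received methotrexate, so the drug's effect itself is not measured here. LPL (ENSG00000175445, chromosome 8, 19759228 to 19824769), the lipoprotein lipase, had 1 count in the 3 libraries with both agents, and its ratio in the methotrexate libraries was 204000 with a counting interval of 36500 to 8040000. ADIPOQ also had 1 count, with a ratio of 103000 (18500 to 4080000). FABP4 (ENSG00000170323, chromosome 8, 82390654 to 82395498), a fatty acid carrier, fell by 16.21 with an SE of 0.62, and the fatty acid transporter CD36 fell by 14.21 with an SE of 0.52. CDKN1A was lower by -6.14 ± 0.12, at 14.6 ± 1.46 CPM with both agents. The largest rises were of 1.70 ± 0.21 for LINC00491 and 1.66 for UCA1 (ENSG00000214049, chromosome 19, 15939757 to 15947130).

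EdgeR called 10576 genes, with 4825 higher and 5751 lower with both agents (45.6% higher). The study's cut-offs on these edgeR results held 4400, with 903 higher and 3497 lower. Under epithelial scaling edgeR called 12254, of which 1.83% were higher, and the median of all genes moved from -0.01 to -0.85. COL15A1 was at least 3000-fold lower with both agents, FCN1 at least 2110-fold, C14orf180 at least 1990-fold, the mesenchymal factor TWIST1 at least 1840-fold, C11orf96 at least 1780-fold and MFAP5 at least 1710-fold. The other named rises were ZNF630 (1.68), DMRTA2 (1.66), TFEC (1.59), WT1 (1.54), P2RY6 (1.54), TMPO-AS1 (from 1.97 to 5.55 CPM), AMACR (1.49) and DSC2 (1.48). All 20 genes with the largest rises and falls kept their call under epithelial scaling. That scaling lowers all genes by less than any of these rises, so the directions were fixed and only the calls of the rises were put to a test. TFRC was at 0.85 ± 0.11, or 0.01 (adjusted p = 0.932) under epithelial scaling. TYMS was at 1.16 ± 0.10 (0.32, adjusted p = 0.0113), MKI67 at 1.36 ± 0.19 and LGR5 at 1.34 ± 0.12 (0.53 and 0.50), FTH1 at -1.74 ± 0.26 and LTF at -3.34 ± 0.41.

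This comparison shares its 3 methotrexate libraries with methotrexate against control, so that features of those libraries appear in it at the opposite sign. Camera called 9 lists up and 12 down, and with an estimated correlation 0 up and 2 down, these being fibroblast markers (0 up and 11 down, also adjusted over the list alone, median -9.85, or -9.46 at the bound, adjusted p = 0.00021) and intestinal lipid handling (6 up and 11 down of 19, or 7 and 11 adjusted over the list alone, median -0.97, adjusted p = 0.0281, or a median of -1.81 with 0 up and 12 down under epithelial scaling). All 27 G2/M genes were higher with both agents, also adjusted over the list alone, with a median of 1.21 (adjusted p = 3.5e-10, and adjusted p = 0.118 with an estimated correlation), or 0.37 with 21 up under epithelial scaling. Of 29 G1/S genes 27 were higher, also adjusted over the list alone, with a median of 0.92 (adjusted p = 2.12e-06, and adjusted p = 0.0747 with an estimated correlation), or 0.09 with 1 up and 3 down under epithelial scaling. Of 26 p53 targets 20 were lower, also adjusted over the list alone, with a median of -0.82 (adjusted p = 6.66e-07, and adjusted p = 0.0747 with an estimated correlation), or -1.67 with 26 down under epithelial scaling. DNA repair (21 up and 2 down of 28, median 0.78), ribosome biogenesis (18 up of 27, median 0.51) and ribosomal proteins (14 up of 26, median 0.31), each also adjusted over the list alone, were higher with TMM, with adjusted p = 0.109, 0.237 and 0.4 with an estimated correlation. They were at -0.06 (2 up, 9 down), -0.33 (17 down) and -0.53 (23 down) under epithelial scaling. Brush border (18 up and 3 down, median 1.01), tight junction (15 up and 2 down, median 0.86) and goblet cell genes (5 up, median 0.93), each also adjusted over the list alone, were higher, with adjusted p = 0.25, 0.0747 and 0.172 with an estimated correlation. Under epithelial scaling they had 2 up and 5 down, 5 up and 5 down, and none called, with medians of 0.18, 0.02 and 0.09. Immediate early and MAPK feedback genes (3 up, 27 down, median -2.05) and NRF2 targets (2 up, 14 down, median -1.08), also adjusted over the list alone, were lower, with adjusted p = 0.109 and 0.0882 with an estimated correlation, and were at -2.89 (1 up, 28 down) and -1.92 (1 up, 17 down) under epithelial scaling. Single libraries ended 4 list calls, namely the Wnt list (adjusted p = 0.0544, 0.0513 and 0.0511 without control 2, control 3 or lactoferrin 3), cholesterol synthesis (0.05, 0.0549 and 0.0507 without control 1, 2 or 3), goblet cell markers (0.0506 without library 1 with both agents) and the integrated stress response (0.0556 without methotrexate 1). Their adjusted p ran from 4.39e-06 to 0.327 over all alternatives. Leaving out single libraries also brought 18 calls to 7 further lists, which were NF-kB (methotrexate 1, 2), interferon (methotrexate 1, 2), heat shock (methotrexate 3), iron (control 1, each lactoferrin library), methotrexate transport (each methotrexate library, libraries 2 and 3 with both agents), pyrimidine synthesis (methotrexate 1) and the unfolded protein response (methotrexate 1, 3, library 3 with both agents), with adjusted p = 0.0156 to 0.0495.

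Adding methotrexate to lactoferrin tested the drug's effect where the protein was present. MSN rose by 2.27 ± 0.27 (adjusted p = 0.00299), VIM by 1.79 ± 0.20 (adjusted p = 0.00299) and LGALS1 by 1.68 ± 0.22 (adjusted p = 0.00756), and these were the only genes edgeR called. TYMS was at 0.20, TFRC at 0.04, FTH1 at -0.18, LTF at 0.29, CDKN1A at -0.23, MKI67 at -0.09 and LGR5 at 0.11, none of them called. No list was called (lowest adjusted p = 0.894), and the fibroblast median was 0.06. The endothelial median of 1.29 is again a fitted value, with no count in lactoferrin for 2 of 4 members and none called. Adjusted p-values for MSN, VIM and LGALS1 without lactoferrin 3 were 0.0572, 0.0531 and 0.0974, and LGALS1 was at 0.0865 without lactoferrin 2, so that 0 genes were called without lactoferrin 3 and 5 without library 3 with both agents, when oxidative phosphorylation also gained a call (0.0164). Over all alternatives the ranges were 1.45e-15 to 0.193 for MSN, 1.6e-09 to 0.883 for VIM and 9.79e-13 to 0.883 for LGALS1. Voom called 0 genes, with 471 at an unadjusted p under 0.05 against 564 with edgeR. edgeR also called 0 when only the 2 compared groups were fitted (unadjusted p under 0.05 for 269) and 0 without the methotrexate libraries (395), so all 3 calls need libraries outside the comparison.

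The interaction, the effect of methotrexate with lactoferrin minus its effect without, was largest in size for transcripts of the methotrexate libraries that were scarce elsewhere. C14orf180, at 90.5 CPM with methotrexate and 0 counts in control, was at -17.39. That fitted value depends on the prior count. Its call was lost without lactoferrin 1, in a group that held 2 counts of this gene in all. CDKN1A was at -6.11 and FTH1 at -2.24, while TYMS was at 1.26, or 0.39 with adjusted p = 0.0281 under epithelial scaling. The largest positive values were 1.98 ± 0.32 for UCA1 (1.10 under epithelial scaling) and 1.80 for ASAH2 (0.93). EdgeR called 7808 genes, with 3444 positive and 4364 negative (44.1% positive), and 10518 with 0.761% positive under epithelial scaling, where the median of all genes moved from -0.04 to -0.90. The study's cut-offs on these edgeR results held 3296.

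Camera called 11 lists positive and 14 negative in the interaction, and with an estimated correlation 2 positive and 8 negative. Both positive ones, G1/S genes (24 up and 0 down of 29, or 27 up adjusted over the list alone, median 0.97, adjusted p = 0.0354 with an estimated correlation) and tight junction genes (15 up and 1 down of 19, also adjusted over the list alone, median 0.95, adjusted p = 0.0375), were at 0.11 and 0.09 under epithelial scaling. The negative ones, with the same counts over all genes and adjusted over the list alone, were fibroblast markers (0 up and 10 down of 11, median -9.18, adjusted p = 0.00277), intestinal lipid handling (6 and 11 of 19, -0.86, adjusted p = 0.00788), NRF2 targets (2 and 13 of 18, -0.97, adjusted p = 0.0282), p53 targets (0 and 18 of 26, -0.94, adjusted p = 0.0354), histone genes (3 and 8 of 15, -0.99, adjusted p = 0.0375), immediate early and MAPK feedback genes (2 and 26 of 32, -1.97, adjusted p = 0.0448), autophagy (1 and 12 of 19, -0.79, adjusted p = 0.0448) and iron handling (5 and 9 of 19, -0.19, adjusted p = 0.0489). Under epithelial scaling, which moves all genes down here, these medians were -10.03, -1.73, -1.84, -1.81, -1.86, -2.84, -1.66 and -1.07. Iron handling was not called at the preset correlation without any of the methotrexate libraries (adjusted p = 0.145, 0.0988 and 0.125, within 2.58e-05 to 0.301 over all alternatives), and neither were NF-kB genes without methotrexate 3 (0.0615) or library 3 with both agents (0.0518), within 0.00228 to 0.199. Heat shock (without control 2 or methotrexate 3, adjusted p = 0.0415 and 0.00975), interferon (lactoferrin 3, methotrexate 1 or 2, adjusted p = 0.0371, 0.0449 and 0.0443) and pyrimidine genes (control 2 or any methotrexate library, adjusted p = 0.0485, 0.017, 0.0278 and 0.023) gained a call, within 0.00163 to 0.452. In this contrast the 3 methotrexate libraries differ from the rest in depth, in mitochondrial share and in fibroblast markers as given above.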

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

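Of the tests reported here, those on RNA of another cell type, on a response with or without lactoferrin, on carry-over and on the 5 genes without the methotrexate libraries were chosen only after the result was seen.

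The interaction contrast was called for 7808 genes. Its 3 methotrexate libraries also differ from the rest in depth, mitochondrial share and fibroblast markers, so the count need not measure a change in the drug's effect. The positive interactions with the largest values were those of UCA1 (1.98), ASAH2 (1.80), EDN3 (1.80), LINC00668 (1.78), EHF (1.76), P2RY6 (1.71), DUOX2 (1.70), GPX2 (1.69), HTR1D (1.69) and ISX (1.68). Under epithelial scaling HTR1D (0.83, adjusted p = 0.096) and ISX (0.82, adjusted p = 0.172) were no longer called. All of these positive values stayed positive, which was fixed because the shift is smaller than any of them. The negative ones with the largest size were C14orf180 (-17.39), PCDH18 (-15.38), CDO1 (-15.09), ADIPOQ (-14.40), SERPINB2 (-14.37), C11orf96 (-14.30), ADAMTS2 (-14.24), ABCD2 (-14.04), FST (-13.99) and LPL (-13.70), fitted values that depend on the prior count. Each of these 10 lost its call (adjusted p = 1) without 1 lactoferrin library. It was library 1 for C14orf180, ADIPOQ, ABCD2 and FST, library 2 for PCDH18, CDO1, C11orf96 and LPL, and library 3 for SERPINB2 and ADAMTS2. LPL had 2 counts in lactoferrin 2 and 0 in lactoferrin 1 and 3, so leaving out library 2 left that group with 0 counts. C14orf180, PCDH18 and ADAMTS2 had 2 counts in all of the lactoferrin group and ADIPOQ 1. With so few counts, these losses do not measure a difference between the lactoferrin replicates. LPL also lost its call without library 1 with both agents (adjusted p = 0.0547). Of the genes always given, CDKN1A was at -6.11, LTF at -3.45, FTH1 at -2.24, TFRC at 0.89, MKI67 at 1.04, TYMS at 1.26 and LGR5 at 1.43. Under epithelial scaling TFRC was at 0.02 and MKI67 at 0.19.

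The same contrast was called for 25 lists with the preset correlation, and 15 of these calls were lost with an estimated correlation. That left 2 positive and 8 negative. Positive medians were 1.18 for G2/M genes, 1.07 for brush border, 0.98 for methotrexate transport, 0.97 for G1/S genes, 0.95 for tight junctions, 0.92 for goblet cell markers, 0.88 for Wnt and stem cell genes, 0.76 for DNA repair, 0.56 for ribosome biogenesis, 0.38 for ribosomal proteins and 0.38 for the unfolded protein response. Under epithelial scaling DNA repair, ribosome biogenesis, ribosomal proteins and the unfolded protein response turned to -0.11, -0.30, -0.49 and -0.49. The other positive medians came to 0.31 for G2/M genes, 0.20 for brush border, 0.12 for methotrexate transport, 0.11 for G1/S genes, 0.09 for tight junctions, 0.05 for goblet cell markers and 0.01 for Wnt and stem cell genes. Negative medians were -9.18 for fibroblast markers, -1.97 for immediate early and MAPK feedback genes, -1.68 for mitochondrially encoded genes, -1.32 for TGF-beta, BMP and YAP targets, -0.99 for histone genes, -0.97 for NRF2 targets, -0.94 for p53 targets, -0.86 for lipid handling, -0.79 for autophagy, -0.68 for hypoxia, -0.57 for NF-kB genes, -0.55 for cholesterol synthesis, -0.41 for the integrated stress response and -0.19 for iron handling. Under epithelial scaling these 14 medians were, in the same order, -10.03, -2.84, -2.55, -2.18, -1.86, -1.84, -1.81, -1.73, -1.66, -1.56, -1.44, -1.41, -1.28 and -1.07. NF-kB genes lost their call without methotrexate 3 (adjusted p = 0.0615) or library 3 with both agents (0.0518), within 0.00228 to 0.199 over all alternatives. Iron handling lost it without methotrexate 1, 2 or 3 (adjusted p = 0.145, 0.0988 and 0.125), within 2.58e-05 to 0.301.

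Of 60 regroupings of the 12 samples, the real one included, 1 gave an interaction count as large as 7808. The highest other count, 7597, came from the only other draw that kept the 3 methotrexate libraries together, and the draws that parted them called 0 genes, so that the count follows a structure of the samples. For the contrasts of 3 against 3, the 10 possible splits are too few for a share under 0.05. The real values were 10791, 0, 5, 10576 and 3 genes, the highest other split gave 0 in each case, and a result as large was found in 1, 10, 1, 1 and 1 of 10 splits.

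The first pattern weighed is that adipocyte and stromal transcripts are abundant in the methotrexate libraries and scarce elsewhere: a list of 16 adipocyte markers, made only once the levels had been seen, summed to 20900 ± 179 CPM by library total with methotrexate, 171 ± 15.4 in control, 184 ± 17.6 with lactoferrin and 169 ± 5.12 with both agents (SD, n = 3), with FABP4 (4250), CD36 (2790) and LPL (2670) the most abundant. Control Caco-2 held 8 of the 16 above 1 CPM, and 0 were in another list. Control 1 held 37 counts of FABP4, 36 of CD36 and 29 of LPL, where controls 2 and 3 held 0 to 5 of each. Of the 2 stromal genes shown per library, COL3A1 showed no such excess, at 34, 37 and 31 counts in controls 1, 2 and 3. SPARC was highest in control 1, at 77 counts against 40 and 53 in controls 2 and 3. The source of these counts was not tested. Against a Caco-2 response to methotrexate that occurs with or without lactoferrin, the log2 ratio of the summed markers between both agents and lactoferrin was -0.12, while between methotrexate and control it was 6.94. RNA of another cell type added to these libraries is a candidate explanation that remains open. Under epithelial scaling, 100% of the called changes over 2-fold were rises among the 10477 genes with an average log2 CPM of at least 3. But the scaling raises all genes alike and the lowest named fall with TMM was -1.59, so this decides nothing. A Caco-2 response that lactoferrin blocks remains open too, since both explanations predict the adipocyte ratios and the extra transcripts occur in 1 group only.

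The second pattern is the 5 genes higher with both agents than in control, all of them abundant in the methotrexate libraries. Carry-over from those libraries would bring their other transcripts too, but the summed adipocyte markers differed from control by -1.24 CPM where the 5 genes' median share of 0.863% (0.256 to 2.66%) predicts 179, or -0.691% of it, and FABP4 was at 0.061 CPM where 36.7 is predicted. A response to methotrexate in the presence of lactoferrin remains open: without the methotrexate libraries the lowest adjusted p was 0.288, and VIM went from 1.69 ± 0.20 to 1.69 ± 0.28, MSN from 2.14 ± 0.26 to 2.13 ± 0.36, LGALS1 from 1.53 ± 0.21 to 1.52 ± 0.27 and AKAP12 from 2.45 ± 0.36 to 2.44 ± 0.44. The call ended as the SE grew at about the same fold, and FBN2 was then below the filter. Over all genes the biological coefficient of variation was 12.2%, against 12.9% in the fit of 12 libraries. Whether the SE grew with fewer libraries, or with the loss of those in which these genes are abundant, was not tested. Over all alternatives the adjusted p ran from 1.08e-09 to 0.681 for VIM, 3.19e-15 to 0.681 for MSN, 1.51e-11 to 0.743 for LGALS1 and 5.17e-12 to 0.743 for AKAP12.

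The third pattern is that the list of immediate early and MAPK feedback genes had a negative median in both groups with lactoferrin. Over the 9 libraries outside the methotrexate group, the list's mean change between the 6 with lactoferrin and the 3 controls was -0.12, and 4 of the 84 splits into 3 and 6 gave a mean as large, the largest other being -0.15. The list was picked from 34 for this pattern, so the splits do not decide whether it arose by chance. A response to lactoferrin may underlie it but is not shown: with an estimated correlation the adjusted p was 0.284, against 7.18e-07 at the preset correlation. Depth ran from 18714054 to 23859094 counts in these 9 libraries, and no batch is given in the labels.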

How the results depend on the processing

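The alternatives without the methotrexate libraries, with epithelial scaling and with thinned methotrexate libraries were tests chosen only after the result was seen; the rest were planned. The total counts for methotrexate against control, both agents against methotrexate and the interaction stayed within 1.5 times under every alternative but the submitters' threshold. Under epithelial scaling these totals held but the directions did not, as given below. The submitters' threshold, put on the edgeR results, gave 4525, 4400 and 3296. It also gave 2 genes for both agents against control, and the small counts moved more. DESeq2 called 15 genes for both agents against control and 7 for both against lactoferrin, and voom called 0 and 0 (unadjusted p under 0.05 for 475 and 471). Without a filter the counts were 17 for lactoferrin, 38 for both against control and 19 for both against lactoferrin, and the cause was not tested. Both of these counts for the 2 agents were 0 in edgeR when only the groups of the contrast were fitted (332 and 269 unadjusted) and 0 without the 3 methotrexate libraries (unadjusted p under 0.05 for 382 and 395 genes). In these fits fewer samples inform the spread, and none from the group where the called genes are most abundant. Sample numbers do not pair the libraries: of 18 same-numbered pairs across groups, residuals correlated across genes at -0.216 to 0.118, with 2 over 0.1. A fit with the replicate number as a block called 3 genes for both against control, 3 for both against lactoferrin and 10371 for methotrexate. Leaving out single libraries gave 0 (control 2) to 8 (library 3 with both agents) genes for both against control, with 3 without control 1 or library 1 with both agents, and 0 (lactoferrin 3) to 5 (library 3 with both agents) for both against lactoferrin. It gave 9984 to 11481 for methotrexate, 9781 to 10895 for both against methotrexate, 6996 to 8216 for the interaction and 0 to 0 for lactoferrin.

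Epithelial scaling, which raises every gene of the methotrexate libraries, left TFRC in methotrexate against control at 0.03 ± 0.11 (adjusted p = 0.819), which is no change. It called 12432, 12254 and 10518 genes for methotrexate, both against methotrexate and the interaction, and thinning called 10461, 10249 and 7672. For methotrexate, epithelial scaling called 12292 higher and 140 lower, against 5922 and 4869 with TMM, and 7791 genes were called with both scalings. For the interaction it called 80 positive and 10438 negative, against 3444 and 4364 with TMM, and 4905 genes were called with both. Of 996 gene results, relative log expression factors left 996 at the same direction and side of the threshold, DESeq2 986, voom 985, no filter 981 and the block 990. Leaving out single libraries left 11870, with 75 calls lost and 7 gained. Of 204 list results, an estimated correlation ended 67 calls, DESeq2 added 21 and voom added 10 and ended 4. Depth limits the scarce genes most: a gene with 0 counts may be at up to 0.0495 to 0.16 CPM, and the folds of such genes are bounds. FBN2 gave no value where only the contrast's groups or the 9 other libraries were fitted, since it was below the filter. The interaction needs 4 groups and has no value from the compared groups alone.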

Other observations

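The tests of the combined lactoferrin libraries were chosen only after the result was seen, except the splits and the list test of the MAPK feedback genes.

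Of 29 tested immediate early and MAPK feedback genes, SPRY4, DUSP6, SPRY2 and MYC are given because they were lower in each of 6 libraries with lactoferrin than in every control, outside the methotrexate group. Other members did not separate in this way or went up: IER2 (-0.33) was lower in 2 of the 6 libraries, and EREG (0.29) and KLF2 (0.27) in 0, each with adjusted p = 0.988. SPRY4 was at -0.66 ± 0.10 (adjusted p = 0.0836). MYC, a growth regulator, lay at 117 to 148 CPM in 6 libraries and 153 to 200 in control (-0.47 ± 0.09, adjusted p = 0.781), DUSP6 at 14.4 to 21.2 against 23.4 to 27.1 (-0.57 ± 0.12, adjusted p = 0.988) and SPRY2 at 21 to 24.8 against 28.8 to 31.2 (-0.38 ± 0.09, adjusted p = 0.988). None passed the test over 15143 genes, which called 0 for lactoferrin over both groups, with 507 at an unadjusted p under 0.05 where 757 would be expected. Oxidative phosphorylation (-0.13) and ribosomal proteins (-0.11) were lower by camera as well, with adjusted p = 7.18e-07 and 1.7e-06, and adjusted p = 0.38 for each with an estimated correlation.

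The adipocyte markers of the methotrexate libraries included the droplet protein PLIN4 at 2450 CPM, the glycerol phosphate dehydrogenase GPD1 at 2520 CPM and ADIPOQ at 1340 CPM by library total, and all 16 were called higher than in control. The 42 brush border and tight junction genes stood at 44.5, 43 and 43.9% of their control CPM in the 3 methotrexate libraries and at 94.2 to 109% in the other 9. Hypoxia and glycolysis genes had library medians of 0.23 in library 3 with both agents, 0.22 in lactoferrin 2 and -0.24 in library 2 with both agents, and of 0.69, 0.53 and 0.67 with methotrexate.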
